A study of Mus musculus with 11 samples.

How the data were processed

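RNA was sequenced from C2C12 cells, a mouse myoblast line, infected at a multiplicity of 100 with an adenovirus that expresses either a short hairpin RNA against Zc3h10 or a scrambled hairpin. Per the labels' protocols, confluent cells received 300 µM 4-thiouridine (4sU) for 30 min, part of each harvest was kept for total RNA, and 4sU-containing RNA was coupled to biotin and recovered on streptavidin. This recovered fraction is called 4sU RNA here. The labels also state that rRNA was removed from total RNA, and that random-primed cDNA was cut with Tn5 transposase and sequenced on a HiSeq2000.

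Each of the 11 libraries came with 2 files, 22 in all, of deposited raw read counts per gene, the first over exons and the second over introns. The counts are whole numbers whose sums differ between libraries, with an Entrez identifier and a gene symbol per the file headers. The exon files list 21677 genes, of which 85 carry no symbol, and the intron files list 18824 genes, of which 63 carry none. Per the submitters' processing notes, reads were aligned to the mouse build mm9 with TopHat2 2.0.8 and TopHat. The counting program, the gene annotation and the use of strand are not given in the sources used here. Genes that overlap, genes with an antisense partner, and genes with near-identical copies (histone, ribosomal protein, ferritin, metallothionein and Gapdh genes among them) therefore have uncertain counts.

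Groups follow GEO's titles and genotype labels: 3 libraries of 4sU RNA labelled shZc3h10, 2 of 4sU RNA labelled scramble, and 3 of total RNA under each label. In all 6 total RNA libraries the file name carries the other hairpin than the label does. Groups were kept as labelled, and directions in total RNA are therefore stated for the libraries labelled with a hairpin. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

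Total counts per library ranged from 10,369,374 to 19,690,198 over exons and from 26,272,902 to 41,597,832 over introns in 4sU RNA. In total RNA they ranged from 31,058,706 to 54,075,687 over exons and from 6,007,028 to 12,213,901 over introns. Replicates of a group differed by more than sampling noise at this depth, by a chi-square per degree of freedom over genes with at least 20 counts in the pair. Between pairs of replicates it ranged from 125 to 459 for exons of total RNA. For exons of 4sU RNA it ranged from 11.0 to 19.2, and for introns of both kinds of RNA from 10.1 to 32.9. This statistic also grows with depth.

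Counts of each kind of RNA were normalised by the trimmed mean of M values and tested with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3. Genes entered after edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. Adjusted p-values are by Benjamini-Hochberg, called below 0.05, and the standard error (SE) of a log2 fold change was derived from the test's F statistic. Fold changes are shZc3h10 minus scramble, as labelled. Levels are CPM, counts scaled to a common normalised library size, as mean ± SD. Where all 11 libraries entered 1 fit, the model had 4 group means. From it came the difference between the hairpin effect in 4sU RNA and in total RNA, and 4sU RNA against total RNA averaged over both hairpins. The change of exons against introns was tested on both counts of each library, with the library as a blocking term.

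Sets of 35 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. Lists needed at least 5 tested members, which 32 lists met in each kind of RNA. The estimated correlation and fry were run beside it. The lists cover respiratory complex I, complexes II and III, complex IV, complex V, the tricarboxylic acid cycle, mitochondrial ribosomal proteins, mitochondrial biogenesis, mitochondrial dynamics and mitochondrial import. They also cover iron, iron-sulphur cluster, haem and cardiolipin genes, fatty acid oxidation, glycolysis, sterol and lipid synthesis, the integrated stress response, endoplasmic reticulum stress, antioxidant genes, p53 targets, cell cycle, histones, cytosolic ribosomal proteins, interferon-stimulated genes, inflammation and immediate early genes. The remainder are myogenic regulators, contractile genes, extracellular matrix, nuclear long non-coding RNAs, markers of adipocytes, osteoblasts, macrophages and endothelium, and mRNAs encoded by the mitochondrial genome. Of the symbols in these lists, 14 had no match in the files: the 13 mitochondrial mRNAs and Col6a3.

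The genes named were set by a rule written before the data were examined, and so were the groups, the tests and most alternatives. For exons of each kind of RNA, the rule takes the 8 largest changes each way among called genes whose groups do not overlap and whose level is at or above the median. For other tests across genes it takes up to 3 each way. For each list it takes up to 3 called members with the smallest p. Zc3h10, Tfrc, Fth1, Ftl1, Slc40a1, Crls1, Taz, Ptpmt1, Ppargc1a, Tfam, Myod1, Myog and Cdkn1a may always be named. Not every gene the rule allows is named. Malat1, Ppp1r8 and Cnn2 lie outside it and were chosen after their values were seen.

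The share of intronic counts was compared between groups by an exact two-sided permutation test. Transcript length and GC content came from the GENCODE M21 annotation, matched by Entrez identifier for 13377 of the 13846 genes tested in total RNA (96.6%). No coordinates were used. One of the genes that the naming rule chose is not reported here. The numbers of the replicates were checked for pairing by the correlation of deviations from group means.

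The scripts were tested on simulated counts with 200 changed genes per comparison, drawn from the means and spread of the real libraries. Genes were drawn independently of each other, and changed genes were not taken from those with the lowest levels. The rates below thus do not cover shifts that many genes of a library share. In simulated total RNA exons (13846 genes), edgeR recovered 23.9% of genes changed 2-fold and 98.5% of those changed 4-fold, and 2.4% of its calls were false. In simulated 4sU RNA exons (13637 genes) it recovered 92.5% and 100%, with 8% false calls. For introns it recovered 38.8% and 92.4% in total RNA (13877 genes; 6.1% false), and 77.6% and 100% in 4sU RNA (13553 genes; 6.8% false). For the difference between both effects (15046 genes) it recovered 4.5% and 87.9%, with 4.6% false. For 4sU RNA against total RNA it recovered 82.1% and 100%, with 4.9% false. For exons against introns it recovered 6% and 68.2% in total RNA (11671 genes; 5.8% false) and 70.1% and 95.5% in 4sU RNA (11610 genes; 6.4% false). DESeq2 1.42.0 made 15.5% false calls in simulated total RNA exons and 20.4% in simulated total RNA introns.

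The alternatives were DESeq2 with its size factors, no filter on low counts, a mean of at least 100 counts, a threshold of 1 on the absolute log2 fold change, each library left out in turn, a replicate block, the sum of the effects in 4sU and total RNA, and the other settings of the gene list tests. Alternatives chosen after seeing the data left out both total RNA libraries numbered 3, or added the intronic percent of each library as a covariate. Leaving out a scramble library of 4sU RNA leaves 1 in that group, which is then assumed to vary like the other group. Alternatives written for normalised units were not used, since the files hold counts.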

Results

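Newly made and total RNA were measured in C2C12 mouse myoblasts after adenoviral delivery of a hairpin against Zc3h10, a gene for a zinc finger protein, or of a scrambled hairpin. The series addresses the part that Zc3h10 plays in mitochondria, in iron and in cardiolipin, the phospholipid of the inner mitochondrial membrane. 4sU RNA, made within 30 min before harvest, came in 3 libraries labelled shZc3h10 and 2 labelled scramble, and total RNA in 3 libraries under each label. Exonic counts per library were 14,319,817, 10,369,374 and 14,675,113 (shZc3h10) and 19,690,198 and 13,611,004 (scramble) in 4sU RNA. In total RNA they were 48,015,125, 51,360,223 and 54,075,687 in the libraries labelled shZc3h10 and 47,854,862, 31,058,706 and 43,606,065 in those labelled scramble. Intronic counts were 26,272,902 to 41,597,832 in 4sU RNA and 6,007,028 to 12,213,901 in total RNA.

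Zc3h10 (Entrez 103284), the gene the hairpin targets, moved in opposite directions in the 2 kinds of RNA. In 4sU RNA its exons stood at 14.9 ± 3.25 CPM in the libraries labelled shZc3h10 (SD, n = 3) and 20.8 ± 0.939 CPM in those labelled scramble (n = 2), a log2 fold change of −0.49 (SE 0.19). Its introns stood at 1.48 ± 0.274 and 2.97 ± 0.474 CPM, a log2 fold change of −0.97 (SE 0.35). In total RNA its exons stood higher in the libraries labelled shZc3h10, at 86.4 ± 25.3 CPM against 41.7 ± 10.2 CPM in those labelled scramble (n = 3 each), a log2 fold change of 1.04 (SE 0.30). Its introns there stood at 43.0 ± 10.3 and 20.5 ± 4.12 CPM, a log2 fold change of 1.07 (SE 0.26). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.128 for exons and 0.0842 for introns in 4sU RNA, and 0.0522 for exons and 0.0325 for introns in total RNA. Exact two-sided permutation tests of CPM gave p = 0.2 and p = 0.1 in 4sU RNA and p = 0.1 for both parts in total RNA, where 0.1 is the smallest p these groups allow. With 1 library left out, the sign held in every fit of these 4 tests, while the calls changed. By edgeR, the adjusted p was 0.0210 for 4sU exons without shZc3h10 library 2 and 0.0371 and 0.0140 for total exons without shZc3h10 library 3 or scramble library 2. The call for total introns was lost (edgeR's adjusted p) without shZc3h10 library 2 (0.194), shZc3h10 library 3 (0.0692), scramble library 1 (0.113) or scramble library 3 (0.0770).

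**Figure D1:**
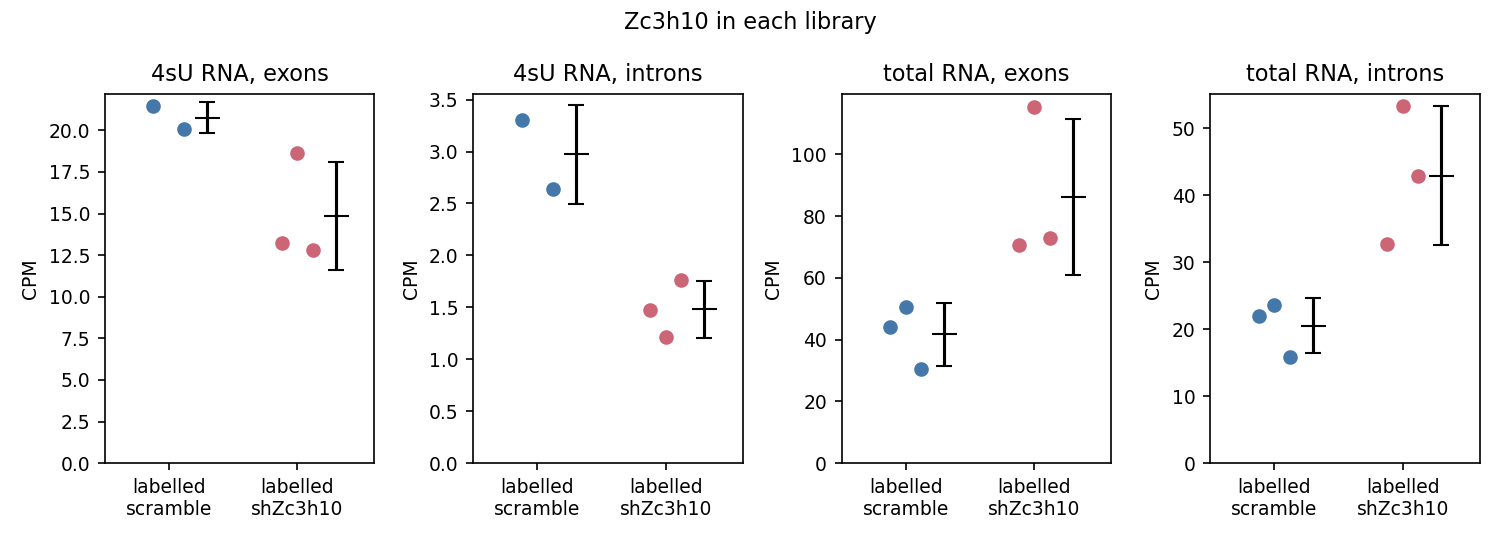
Zc3h10 in each library, in CPM on a linear axis, for exons and introns of 4sU and total RNA; dots are libraries and bars the mean with SD. Zc3h10 exons average 14.9 CPM with shZc3h10 and 20.8 CPM with scramble in 4sU RNA, but 86.4 and 41.7 CPM under the same labels in total RNA.

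Directions in 4sU RNA hold for the labels too, since edgeR did not call the lower Zc3h10 there (adjusted p = 0.128 for exons, 0.0842 for introns). Genes that rose or fell did so in libraries labelled shZc3h10 against those labelled scramble. Among the genes that the naming rule chose from this comparison of newly made RNA, Fmod, Aoc3 and Nkd2 rose most. Nptx1, Msln and Sema3c fell most. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, rose from 3.37 ± 0.841 CPM with scramble (n = 2) to 50.1 ± 10.7 CPM (n = 3), a log2 fold change of 3.92 (SE 0.24). Prelp, another matrix proteoglycan, rose from 60.2 to 308 CPM (2.35, SE 0.15). The Wnt antagonists Nkd2 and Sfrp2 rose by 2.59 (SE 0.17) and 2.38 (SE 0.21) on the log2 scale, and the growth factors Bmp4 and Igf2 rose by 2.35 (SE 0.16) and 2.23 (SE 0.17). Aoc3, for an amine oxidase, rose by 2.65 (SE 0.16), and Mylk, for the kinase of myosin light chains, by 2.21 (SE 0.17). Nptx1, for a neuronal pentraxin, went from 80.7 ± 10.8 to 12.4 ± 4.02 CPM, a log2 fold change of −2.71 (SE 0.21). The mesothelin gene Msln fell by 2.23 (SE 0.15), the axon guidance gene Sema3c by 2.03 (SE 0.17), and the muscle genes Klhl30 and Synpo2l by 1.71 (SE 0.15) and 1.65 (SE 0.17). Krt80 fell by 1.68 (SE 0.14), Nefl by 1.62 (SE 0.20) and Prrg4 by 1.56 (SE 0.16). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 16 genes ran from 2.87e-09 (Fmod) to 9.78e-06 (Nefl), and each was called with any 1 library left out. Of 13637 genes tested, 772 rose and 640 fell, with a median fold of 1.77 among the 1412 called. The count was 724 without scramble library 1 and 924 without shZc3h10 library 3.

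Among the gene lists, extracellular matrix genes rose in 4sU RNA and cell cycle and integrated stress response genes fell. Of 25 matrix genes tested, 14 rose and 0 fell (15 and 1 adjusted over the list alone), among them Col6a2 (1.26, SE 0.14), Col6a1 (1.07, SE 0.14) and the smooth muscle gene Tagln (1.17, SE 0.15). The list's adjusted p by camera was 1.05e-10, adjusted p = 0.145 with an estimated correlation. Of 38 cell cycle genes, 0 rose and 16 fell (0 and 20 adjusted over the list alone), among them the cyclins Ccna2 (−0.78, SE 0.15) and Ccne2 (−0.69, SE 0.15; edgeR's adjusted p was 0.0650 without scramble library 2) and the spindle gene Tpx2 (−0.66, SE 0.15; 0.182 without scramble library 1). The list's adjusted p by camera was 1.05e-10, adjusted p = 0.471 with an estimated correlation. Of 25 integrated stress genes, which answer to the factor ATF4, 0 rose and 9 fell (0 and 10 adjusted over the list alone), among them Stc2 (−1.71, SE 0.23), Atf3 (−1.37, SE 0.14) and Psat1 (−1.06, SE 0.14). The list's adjusted p by camera was 7.11e-07, adjusted p = 0.471 with an estimated correlation. These 3 lists were called with any 1 library left out, while the genes called in such fits ran from 9 to 14 for matrix, 4 to 17 for cell cycle and 3 to 9 for integrated stress.

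A further 6 lists were called in 4sU RNA by camera with its preset correlation, and each lost its call without at least 1 library. Inflammation genes rose, 5 of 18 up and 0 down (6 and 1 adjusted over the list alone), with the chemokines Cxcl5 (1.41, SE 0.24) and Ccl7 (1.20, SE 0.22) and the growth factor Csf1 (0.70, SE 0.15). The adjusted p by camera was 0.0261, adjusted p = 0.471 with an estimated correlation, and 0.0567 without shZc3h10 library 2 or 0.0756 without scramble library 2. Of 20 immediate early genes, 7 rose and 5 fell (11 and 5 adjusted over the list alone), with Egr2 (1.33, SE 0.14), Fos (1.11, SE 0.14) and Nr4a1 (0.92, SE 0.15) among those that rose. This list had an adjusted p of 0.0261 by camera, adjusted p = 0.777 with an estimated correlation, and 0.0622, 0.0578 or 0.450 without shZc3h10 library 2, shZc3h10 library 3 or scramble library 2. Of 21 p53 targets, 1 rose, Fas (2.18, SE 0.31), and 4 fell (1 and 5 adjusted over the list alone), with Pmaip1 (−1.11, SE 0.14), Cdkn1a (−0.87, SE 0.15) and Plk2 (−0.82, SE 0.13). For the p53 list, camera's adjusted p was 0.0331, adjusted p = 0.471 with an estimated correlation, and 0.0544, 0.0622 or 0.0814 without shZc3h10 library 1, shZc3h10 library 2 or scramble library 1. Of 27 contractile genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone), with the sarcomere gene Ttn (−1.08, SE 0.14) and the calcium channel gene Ryr1 (−0.77, SE 0.15) among those that fell. For contractile genes, camera's adjusted p was 0.0337, adjusted p = 0.479 with an estimated correlation, and 0.0865 or 0.105 without shZc3h10 library 1 or scramble library 1. With 1 library left out, edgeR called 3 to 6 inflammation genes, 8 to 13 immediate early genes, 5 to 6 p53 targets and 3 to 9 contractile genes.

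Of 22 glycolysis genes, 2 rose and 4 fell in 4sU RNA (2 and 7 adjusted over the list alone). Gapdh, whose many processed copies make its counts uncertain, fell by 0.60 (SE 0.14) and Gpi1 fell by 0.53 (SE 0.14). By edgeR, both lost their call without shZc3h10 library 3 (adjusted p = 0.0621 and 0.0850), Gapdh also without scramble library 1 (0.233) and Gpi1 without scramble library 2 (0.205). Camera's adjusted p for glycolysis was 0.0331, adjusted p = 0.471 with an estimated correlation, and 0.0747 or 0.105 without shZc3h10 library 2 or scramble library 1. Of 17 endoplasmic reticulum stress genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone), with the chaperone gene Hyou1 at −0.61 (SE 0.16; edgeR's adjusted p was 0.461 without scramble library 1). Camera's adjusted p for that list was 0.0136, adjusted p = 0.643 with an estimated correlation, and 0.265 without scramble library 1. With 1 library left out, edgeR called 0 to 5 glycolysis genes and 0 to 6 endoplasmic reticulum stress genes.

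The iron, cardiolipin and mitochondrial lists that the series' question concerns were not called in 4sU RNA by camera. Of 21 iron genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone; 0 rose without shZc3h10 library 3), with an adjusted p of 0.614 by camera. The iron exporter gene Slc40a1 rose by 0.76 (SE 0.20) and the importer gene Slc39a14 by 0.58 (SE 0.14). By edgeR, Slc40a1 lost its call without shZc3h10 library 3 (adjusted p = 0.0899) or scramble library 2 (0.131), and Slc39a14 without shZc3h10 library 3 (0.0539) or scramble library 1 (0.190). The median log2 fold change of the iron list was −0.01, its mean 0.06, and camera's direction up. The transferrin receptor gene Tfrc stood at −0.36 (edgeR's adjusted p = 0.195), and the ferritin genes Fth1 and Ftl1, which have near-identical copies, at 0.00 and −0.37. The cardiolipin synthase gene Crls1 stood at −0.52 (edgeR's adjusted p = 0.123), Taz at −0.10 and Ptpmt1 at 0.29. The regulators of mitochondrial biogenesis Ppargc1a and Tfam stood at 0.28 and 0.04, and the myogenic factors Myod1 and Myog at 0.03 and −0.22, none called by edgeR. Complex I had 1 of 36 genes called, Ndufv3 (0.80, SE 0.20; 1 up and 0 down adjusted over the list alone), which lost its call without shZc3h10 library 3 (edgeR's adjusted p = 0.0581) or scramble library 2 (0.123). Complexes II and III (14 genes), complex IV (12), complex V (16), the tricarboxylic acid cycle (23), mitochondrial ribosomal proteins (75), biogenesis (18), dynamics (15) and import (26) had 0 genes called by edgeR. So had iron-sulphur cluster (20), haem (12) and cardiolipin (17) genes, histones (29), cytosolic ribosomal proteins (80) and osteoblast markers (5). Over these 14 lists and their 362 tested entries, 24 had an unadjusted p below 0.05 by edgeR and 1 was called by DESeq2, and with 1 library left out edgeR called at most 2 genes of any of them.

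Other lists were not called in 4sU RNA by camera but held called genes. Of 25 sterol and lipid genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone), and 1 to 2 fell with any 1 library left out. Of 21 myogenic regulators, 1 rose and 5 fell (1 and 7 adjusted over the list alone): Igf2 rose, and the myoblast surface genes Itga7 (−1.11, SE 0.13) and Cdh15 (−0.93, SE 0.14) fell, with 4 to 8 genes called when 1 library was left out. Camera's adjusted p was 0.0851 for each of these lists. Interferon-stimulated genes had 2 of 22 up (2 and 0 adjusted over the list alone; camera's adjusted p = 0.147), and 0 without shZc3h10 library 3, scramble library 1 or scramble library 2. Fatty acid oxidation had 1 up and 2 down of 19 (2 and 2 adjusted over the list alone; camera's adjusted p = 0.938), with a median of 0.03, a mean of −0.01 and camera's direction up. Its gene Acadl stood at −0.78 (SE 0.15), called by edgeR except without scramble library 1 (adjusted p = 0.0753), while Echs1 and Cpt1b were called in 1 of 5 such fits each. Antioxidant genes had 1 of 20 up (1 and 0 adjusted over the list alone; camera's adjusted p = 0.614), and 0 up without shZc3h10 library 3, scramble library 1 or scramble library 2. Of 8 nuclear long non-coding RNAs, 0 rose and 1 fell, Neat1 (0 and 1 adjusted over the list alone; −0.58, SE 0.15). Neat1 lost its call without shZc3h10 library 3 (edgeR's adjusted p = 0.112) or scramble library 1 (0.284), and the list had a median of −0.03, a mean of 0.05 and camera's direction down (adjusted p = 0.766). Among markers of other cell types, 1 of 6 adipocyte genes rose, the lipase gene Lpl (1.62, SE 0.14; 1 and 0 adjusted over the list alone), with an adjusted p of 0.0851 by camera. Macrophage and endothelial markers had 4 tested genes each, too few for the list test, and none of them was called by edgeR. The mRNAs of the mitochondrial genome are not analysed here.

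In total RNA the libraries labelled shZc3h10 had more Nptx1, Sema3c and Msln and less Fmod, Nkd2 and Mylk than those labelled scramble, the opposite of 4sU RNA. Zc3h10 goes against the labels in total RNA, so every direction in total RNA holds for the labels only. Fmod stood at 4.91 ± 0.824 CPM in the libraries labelled shZc3h10 and 64.2 ± 7.74 CPM in those labelled scramble (n = 3 each), a log2 fold change of −3.71 (SE 0.28). The natriuretic peptide receptor gene Npr3 stood at −2.91 (SE 0.33), Sfrp2 at −2.86 (SE 0.36), Rgs4 at −2.78 (SE 0.34), the matrix genes Col8a2 and Aspn at −2.77 (SE 0.35) and −2.53 (SE 0.32), Nkd2 at −2.56 (SE 0.28) and Mylk at −2.50 (SE 0.32). Nptx1 stood at 163 ± 132 CPM in the libraries labelled shZc3h10 and 13.3 ± 1.72 CPM in those labelled scramble, a log2 fold change of 3.63 (SE 0.48). Its levels in shZc3h10 libraries 1, 2 and 3 were 85.7, 87.8 and 315 CPM, and without library 3 its log2 fold change was 2.77. Sema3c stood at 2.78 (SE 0.35), the urea transporter gene Slc14a1 at 2.76 (SE 0.36), Klhl30 at 2.28 (SE 0.35), Msln at 2.26 (SE 0.29), Prrg4 at 2.13 (SE 0.32) and Krt80 at 2.08 (SE 0.32). The cytokine receptor gene Il2rg stood at 2.24 (SE 0.37). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 16 genes ran from 2.12e-05 (Fmod) to 0.00372 (Il2rg), and Il2rg alone lost its call in a fit with 1 library left out (0.0584 without scramble library 3). Of 13846 genes tested, 424 were higher and 465 lower, 889 in all, with a median fold of 2.69. DESeq2 called 1096 higher and 781 lower, and with the replicate number as a block edgeR called 100. Without shZc3h10 libraries 1 or 2, edgeR's count was 432 or 541, and without scramble libraries 1, 2 or 3 it was 201, 2588 or 126.

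Camera called the integrated stress, cell cycle and matrix lists in total RNA in the opposite direction to 4sU RNA, but other groupings of the same libraries called as many lists. Of the 10 splits of the 6 libraries into 3 and 3, 6 called at least the 6 lists of the real split, and the highest called 17. Of 25 integrated stress genes, 7 were higher in the libraries labelled shZc3h10 and 0 lower (9 and 0 adjusted over the list alone), with the hormone gene Fgf21 at 1.52 (SE 0.26). By camera, that list had an adjusted p of 3.88e-04, adjusted p = 0.918 with an estimated correlation. Of 38 cell cycle genes, 2 were higher and 0 lower (0 and 0 adjusted over the list alone), with camera's adjusted p = 0.00336, adjusted p = 0.918 with an estimated correlation. The genes called were Rrm1 (1.35, SE 0.36) and Ccne2 (1.47, SE 0.41), and edgeR's calls of both were lost without shZc3h10 library 2 (adjusted p = 0.0710 and 0.141), scramble library 1 (0.159 and 0.179) or scramble library 3 (0.170 and 0.234). That of Ccne2 was also lost without shZc3h10 library 1 (0.0887). Of 25 matrix genes, 0 were higher and 5 lower (0 and 8 adjusted over the list alone), with Col6a1 at −1.96 (SE 0.30) and Col1a1 at −1.32 (SE 0.31). By edgeR, Col1a1 lost its call without shZc3h10 library 1 or 2 (adjusted p = 0.0626 and 0.0861) or scramble library 1 or 3 (0.126 and 0.127). The adjusted p of the list by camera was 0.00471, adjusted p = 0.918 with an estimated correlation. Of 81 cytosolic ribosomal protein genes, 0 were higher and 2 lower (2 and 30 adjusted over the list alone), Rpl39 (−1.52, SE 0.38) and Rps21 (−1.86, SE 0.47), with camera's adjusted p = 5.08e-07, adjusted p = 0.918 with an estimated correlation. EdgeR's calls of Rpl39 and Rps21 were lost without shZc3h10 library 1 (adjusted p = 0.0542 and 0.0539), shZc3h10 library 3 (0.108 and 0.114), scramble library 1 (0.155 for both) or scramble library 3 (0.191 and 0.216). These 4 lists were called by camera with any 1 library left out, while the genes called by edgeR in such fits ran from 1 to 8 for integrated stress, 0 to 6 for cell cycle, 1 to 6 for matrix and 0 to 44 for ribosomal proteins. DESeq2 called 9 integrated stress, 8 cell cycle, 9 matrix and 19 ribosomal protein genes. Ribosomal protein and histone genes have near-identical copies, so their counts are uncertain.

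Camera at its preset correlation also called the histone and complex I lists downward in total RNA, with less stable list calls. Few of their single genes were called by edgeR, while DESeq2 called 10 histone and 6 complex I genes. Of 49 histone genes, 0 were higher and 2 lower (0 and 0 adjusted over the list alone), Hist1h2bk (−1.69, SE 0.42) and Hist1h2ak (−1.65, SE 0.46). For histones, camera's adjusted p was 3.94e-04, adjusted p = 0.918 with an estimated correlation, and 0.186 without scramble library 1. Of 36 complex I genes, 1 was higher, Ndufs8 (1.28, SE 0.35), and 1 lower, Ndufa13 (−1.61, SE 0.38), with 1 and 5 adjusted over the list alone. Camera's adjusted p was 0.0210, adjusted p = 0.918 with an estimated correlation, and 0.222, 0.168 or 0.133 without shZc3h10 library 3, scramble library 1 or scramble library 3. Without scramble library 2 edgeR called 29 histone and 14 complex I genes, and without scramble library 1 or 3 it called 0 of either. By edgeR, Hist1h2bk and Hist1h2ak were called with scramble library 2 left out and lost without any other (adjusted p from 0.0545 to 0.186 and from 0.0608 to 0.236). Ndufa13 lost its call without shZc3h10 library 3 (edgeR's adjusted p = 0.0849), scramble library 1 (0.138) or scramble library 3 (0.160), and Ndufs8 without shZc3h10 library 1 (0.0621), shZc3h10 library 2 (0.0920), scramble library 1 (0.212) or scramble library 3 (0.171). The share of intronic reads, which differed within the scramble group, was 15.3%, 16.2% and 21.9% in scramble libraries 1, 2 and 3 and 13.8%, 10.7% and 11.2% in those labelled shZc3h10. Without both libraries numbered 3, which lay farthest apart on the first principal component, camera's adjusted p was 0.577 for complex I and 0.0693 for histones. That fit called 9 lists, and only 4 of them were among the 6 called with all libraries.

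The other lists were not called by camera in total RNA. Inflammation had 0 of 17 higher and 5 lower (0 and 5 adjusted over the list alone; camera's adjusted p = 0.111), with Cxcl5 at −2.38 (SE 0.34). Adipocyte markers had 0 of 6 higher and 2 lower (1 and 3 adjusted over the list alone; camera's adjusted p = 0.121), with Lpl at −1.89 (SE 0.25). Antioxidant genes had 2 of 20 higher (2 and 0 adjusted over the list alone; camera's adjusted p = 0.287), Nqo1 (1.3, SE 0.27) and Cat (1.20, SE 0.32). By edgeR, both calls were lost without scramble library 1 (adjusted p = 0.0956 and 0.162) or scramble library 3 (0.0799 and 0.172), and that of Cat also without shZc3h10 library 1 (0.0673) or 2 (0.0719). The p53 targets had 2 higher and 1 lower of 21 (3 and 2 adjusted over the list alone; camera's adjusted p = 0.691), with Cdkn1a at 1.32 (SE 0.29), lost by edgeR without shZc3h10 library 1 (adjusted p = 0.0542), scramble library 1 (0.0691) or scramble library 3 (0.101). Myogenic regulators had 2 higher and 1 lower of 22 (3 and 2 adjusted over the list alone; camera's adjusted p = 0.910), with Igf2 at −1.80 (SE 0.32). Mitochondrial ribosomal proteins had 3 of 76 higher (3 and 0 adjusted over the list alone; camera's adjusted p = 0.780), with Mrps6 at 1.63 (SE 0.32), lost by edgeR without scramble library 1 (adjusted p = 0.0785) or 3 (0.0838). Complex IV had 1 of 12 higher (1 and 6 adjusted over the list alone; camera's adjusted p = 0.353), Cox6a1 (1.90, SE 0.51), whose change was 0.87 and not called without shZc3h10 library 3 (edgeR's adjusted p = 0.0890). The tricarboxylic acid cycle (23 genes), biogenesis (18), import (26), iron (22) and cardiolipin (17) had 1 gene higher each, over all genes and adjusted over the list alone. Sterol and lipid synthesis (25) and contractile genes (30) had 1 higher each and 0 adjusted over the list alone. Interferon (24) and osteoblast (6) genes had 1 lower each, and 2 and 1 lower adjusted over the list alone. Without scramble library 1 or 3, edgeR called 1 gene each of inflammation, myogenic regulators and adipocyte markers and 0 of every other list in this group. Tfrc stood at 0.88 (edgeR's adjusted p = 0.112), or 0.0343 without shZc3h10 library 3 and 0.0374 without scramble library 2.

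Among the mitochondrial and iron genes that are always reported, none was called in exons of total RNA with all 6 libraries. Slc40a1 stood at −0.39, Fth1 at 0.09, Ftl1 at 0.11, Crls1 at −0.92 (edgeR's adjusted p = 0.215), Taz at −0.33, Ptpmt1 at −0.79 (called by edgeR without scramble library 2, adjusted p = 0.0423), Ppargc1a at 0.36, Tfam at −0.69, Myod1 at −0.29 and Myog at −0.10. In 10 lists edgeR called 0 genes: complexes II and III (14), complex V (16), dynamics (14), iron-sulphur cluster (20), haem (12), fatty acid oxidation (19), glycolysis (22), endoplasmic reticulum stress (17), immediate early (20) and nuclear long non-coding RNA (7). Over their 161 tested entries, 38 had an unadjusted p below 0.05 by edgeR and 18 were called by DESeq2. With 1 library left out edgeR called at most 6 genes of any of them, in fatty acid oxidation without scramble library 2. Adjusted over the list alone, complexes II and III had 2 higher and 3 lower, immediate early genes 2 and 4, and the other 8 lists 0. Macrophage and endothelial markers were too few to test as lists, and edgeR called none of their genes. The list's median, mean and camera's direction differed in sign for iron (−0.01, 0.00, up) and cardiolipin (−0.13, 0.03, up). Camera pointed up while median and mean were negative for mitochondrial ribosomal proteins (−0.23 and −0.07), haem (−0.04 and −0.06), endoplasmic reticulum stress (−0.36 and −0.08), p53 targets (−0.02 and −0.03) and myogenic regulators (−0.10 and −0.07). Camera weighs a list against the other genes, and the median log2 fold change of all genes tested in total RNA was −0.10. DESeq2's scaling shifted the changes there by a median of 0.065. Under it the medians of the iron, haem, p53 and immediate early lists changed sign in total RNA. No list median changed sign in 4sU RNA.

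**Figure D2:**
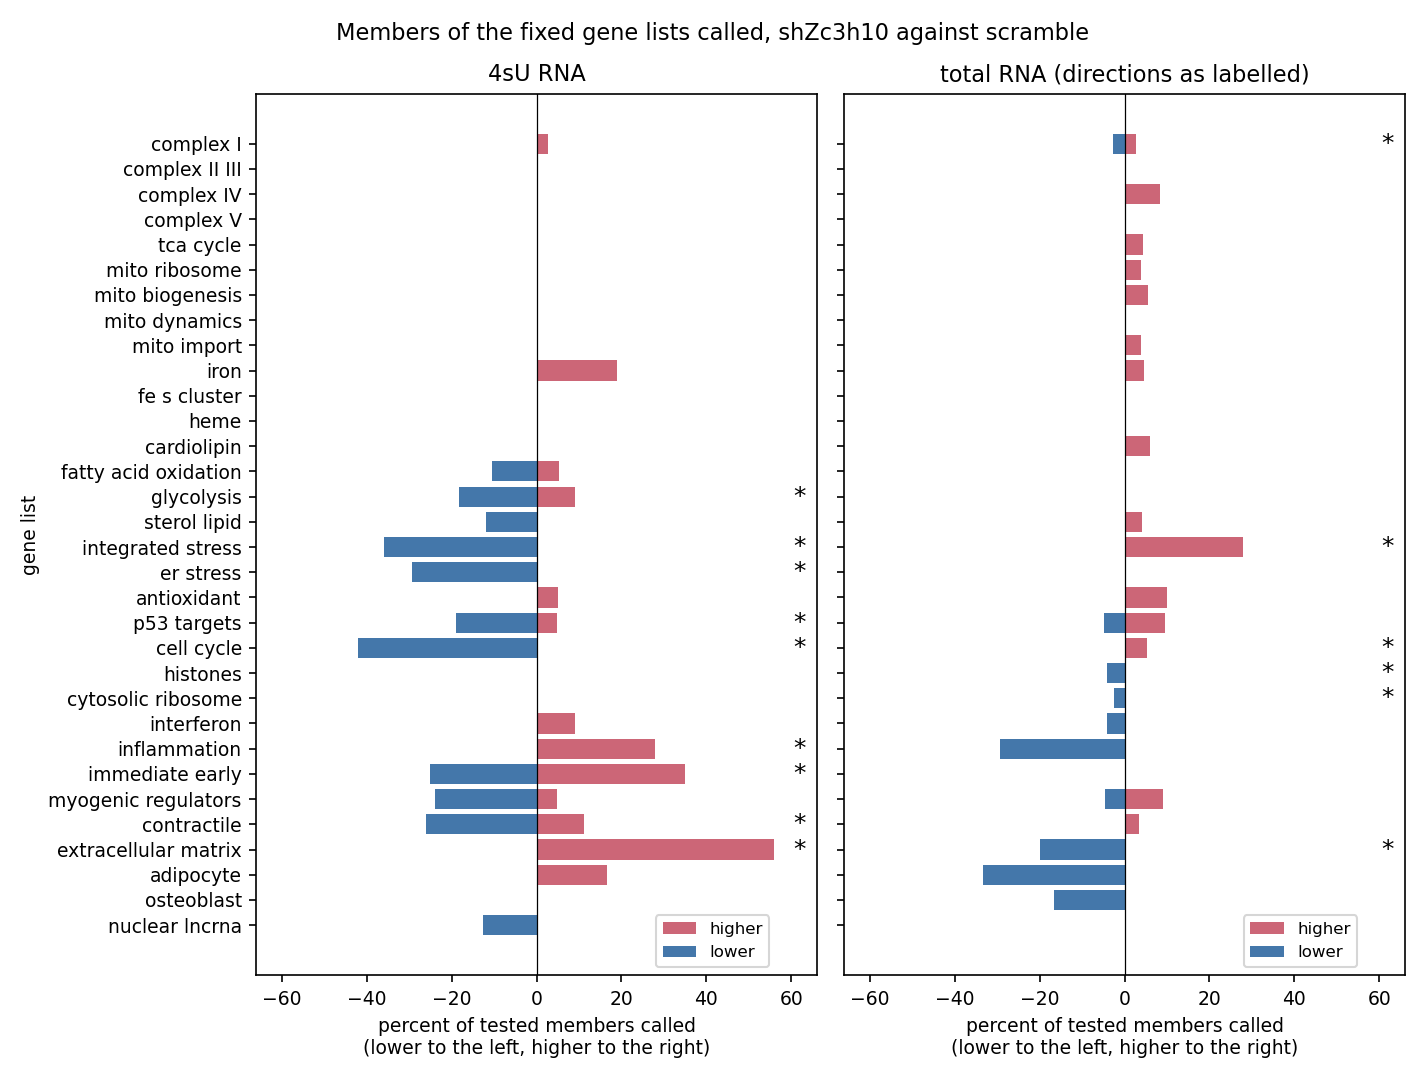
Percent of the tested genes of each list called higher or lower with shZc3h10 by edgeR, in 4sU RNA (n = 3 and 2) and in total RNA as labelled (n = 3 each); an asterisk marks a list called by camera. Matrix genes rise in 4sU RNA (14 of 25) and are lower in total RNA labelled shZc3h10 (5 of 25).

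Introns, which report unspliced RNA, were tested apart from exons. In 4sU RNA the introns of Nkd2 rose by 2.87 (SE 0.10), those of the basement membrane gene Lama1 by 2.73 (SE 0.15) and those of Emid1 by 2.58 (SE 0.15). The introns of Sema3c fell by 1.97 (SE 0.11), and those of the muscle genes Xirp2 and Tmem182 by 1.94 (SE 0.17) and 1.84 (SE 0.14). In total RNA, in the libraries labelled shZc3h10, introns of Msln stood at 2.81 (SE 0.32), Klhl30 at 2.33 (SE 0.19), Serpinb9b at 2.03 (SE 0.27), Il1rn at −2.61 (SE 0.30), Nkd2 at −2.31 (SE 0.22) and Itga1 at −2.22 (SE 0.25). All 12 of these intron changes were called by edgeR's quasi-likelihood test with any 1 library left out, with adjusted p at most 1.29e-05 in 4sU RNA (Xirp2) and 7.40e-04 in total RNA (Serpinb9b). Introns of the ferritin gene Ftl1 fell by 0.64 (SE 0.13; edgeR's adjusted p = 0.00400, or 0.0653 without scramble library 1) in 4sU RNA. In total RNA they stood at 0.90 (SE 0.24; edgeR's adjusted p = 0.0455), a call lost when any library but shZc3h10 library 3 was left out. In 4sU RNA, 1213 of 13553 genes rose and 890 fell (2103 called, 935 without scramble library 1). In total RNA, 427 of 13877 genes were higher and 292 lower (719 called), and the count was 376, 228 or 217 without shZc3h10 library 1, shZc3h10 library 2 or scramble library 1. Of the genes called in exons and tested in introns, 898 of 1264 in 4sU RNA and 230 of 756 in total RNA were called in introns too, all in the direction of the exons. Across genes Pearson's r of the exon and intron changes was 0.70 and 0.51. Genes are not independent replicates.

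The hairpin effect, taken with the labels as given, ran in opposite directions in newly made and in total RNA. Of 452 genes called in exons of both, 451 went opposite ways (99.8%, exact Clopper-Pearson 95% interval 98.8 to 99.99%) and 1, Ppp1r8, went the same way. That interval takes genes as independent, though all share the same libraries, so it does not measure the spread between libraries. Those higher in total RNA and lower in 4sU RNA numbered 170, and those lower and higher 281, where independent lists would share 20.1 and 26.1. Pearson's r of both changes was −0.51 and Spearman's rho −0.42 across 13100 genes, which are not independent replicates. For introns, 482 of 483 genes went opposite ways, all but Cnn2. The difference between both effects was 7.47 (SE 0.40) for Fmod, 5.32 (SE 0.56) for Rgs4 and 5.29 (SE 0.40) for Lama1. It was −6.46 (SE 0.61) for Nptx1, −4.96 (SE 0.40) for Sema3c, −4.64 (SE 0.33) for Msln, and −1.68 (SE 0.38) for Zc3h10. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these 7 differences had adjusted p from 7.56e-09 (Fmod) to 0.00677 (Zc3h10) and were called in 11 of 11 fits with 1 library left out. Of 15046 genes, 835 differed upward and 1288 downward, 2123 in all. That count was 1415, 1029 or 1123 without 4sU shZc3h10 library 3 or 4sU scramble libraries 1 or 2, and 3246 without total scramble library 2. When both effects were summed, so that opposite effects cancel, edgeR called 0 genes, with 1707 at an unadjusted p below 0.05 (11.3%), and DESeq2 called 78.

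**Figure D3:**
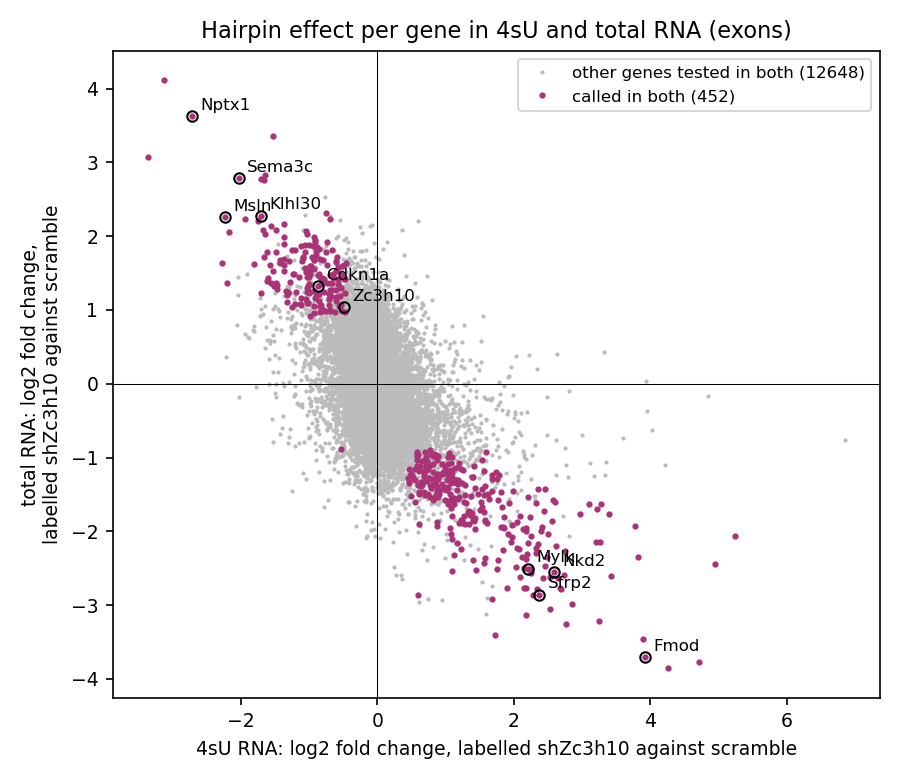
Log2 fold change (shZc3h10 minus scramble, as labelled) of exons in 4sU RNA on the horizontal axis and in total RNA on the vertical axis, 1 point per gene, with the 452 genes called in both marked. Of these, 451 lie in the quadrants of opposite sign.

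**Figure D4:**
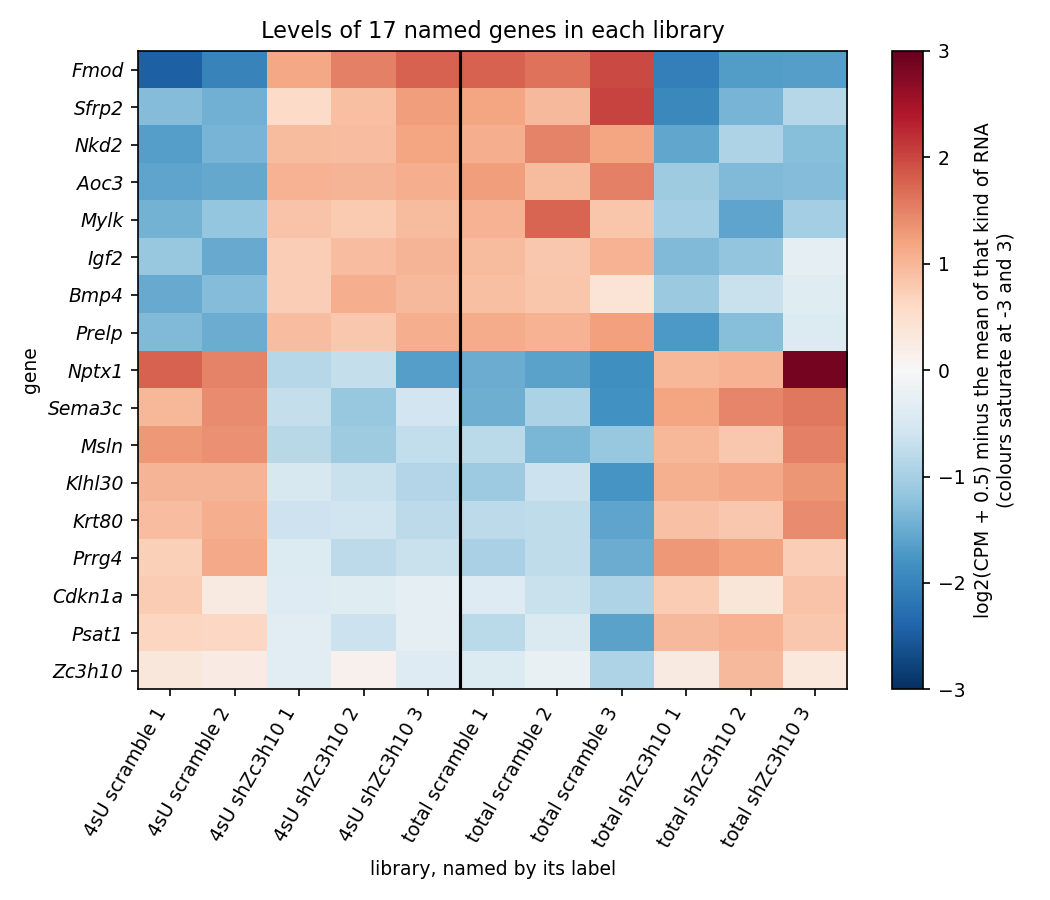
Heat map of 17 genes in the 11 libraries, as log2 of CPM plus 0.5 minus the mean of that kind of RNA, with colours saturating at 3 either way. Fmod is high in 4sU RNA labelled shZc3h10 and in total RNA labelled scramble, and Nptx1 shows the reverse.

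Averaged over both hairpins, 4sU RNA differed from total RNA in most genes. Epm2aip1 was enriched in 4sU RNA by 4.64 (SE 0.20) on the log2 scale, Zbtb34 by 4.11 (SE 0.22) and Eid3 by 3.96 (SE 0.26). Tmem132a stood at −5.40 (SE 0.29), the mitochondrial ribosomal gene Mrps21 at −4.91 (SE 0.32), the methyl cycle gene Ahcy at −4.85 (SE 0.27) and Zc3h10 at −2.56 (SE 0.21). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5275 genes were higher and 5402 lower of 15046, and the 7 genes named were called in 11 of 11 fits with 1 library left out. Introns took 69.9 ± 1.67% of counts in 4sU RNA (n = 5) and 14.8 ± 4.09% in total RNA (n = 6), a difference of 55.0 points with an exact permutation p of 0.00216, the smallest possible. The nuclear RNA Malat1 took 1.33 to 1.78% of exonic counts in 4sU RNA and 0.0779 to 0.522% in total RNA.

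The intronic share stood higher in the 4sU RNA libraries labelled shZc3h10, and lower in the total RNA libraries with that label. In 4sU RNA it was 71.0 ± 0.772% (n = 3) against 68.1 ± 0.378% (n = 2), a difference of 2.86 points, and in total RNA 11.9 ± 1.68% against 17.8 ± 3.55% (n = 3 each), a difference of −5.93 points. Exact two-sided permutation tests gave p = 0.1 for each, the smallest that these groups allow. Few single genes were called for a change in exons beyond introns, in a test that recovered 6% of simulated 2-fold changes in total RNA and 70.1% in 4sU RNA. In 4sU RNA edgeR called 17 of 11812 genes, 5 up and 12 down, with Fgd4 at 1.24 (SE 0.13; adjusted p = 6.23e-04) and Itga3 at −1.02 (SE 0.14; adjusted p = 0.00405), both called with any 1 library left out. The metallothionein gene Mt1 stood at 1.33 (SE 0.19; edgeR's adjusted p = 0.00657, or 0.146 without scramble library 1). The count was 5, 7 and 6 without shZc3h10 libraries 1, 2 and 3 and 2 without scramble library 1. In total RNA edgeR called 4 of 11891 genes, 2 up and 2 down (2150 at an unadjusted p below 0.05), with Bcap29 at 2.08 (SE 0.30) and Fmod at −2.36 (SE 0.35) in the libraries labelled shZc3h10, both with adjusted p = 0.0365. Leaving out any total RNA library but scramble library 2 left 0 genes called by edgeR, with 1243 to 1976 at an unadjusted p below 0.05, and the highest adjusted p of both genes was 0.261, without scramble library 1. Without scramble library 2 the count was 615. DESeq2 called 410 genes in total RNA, 250 up and 160 down, and 44 in 4sU RNA.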

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

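Both tests of an exchange of labels were chosen after the opposite directions had been seen, while the test of RNA synthesis against stability was planned. The hairpin effect on exons differed between 4sU RNA and total RNA for 2123 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 80 of them among the genes reported singly. Each value here is the difference of both effects on the log2 scale, 4sU minus total RNA with the labels as given. Adjusted p by edgeR ran from 7.56e-09 for Fmod to 0.0429 for Ndufa13. With each of the 11 libraries left out in turn, all 80 kept their sign and 65 were called in every fit. Of the other 15, Ndufa13, Echs1 and Tfrc were called in 3 of 11 fits, Cox6a1 in 4, Cat and Acadl in 5, and the rest in 7 to 10. Cox6a1 ranged from −2.42 to −1.0 over these fits.

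Positive differences mean a higher change in 4sU RNA than in total RNA, whether or not either change was called. Matrix and adhesion genes among them include Fmod (7.47), Lama1 (5.29), Itga1 (4.92), Col8a2 (4.78), Prelp (4.40), Emid1 (4.27), Aspn (3.46), Col6a1 (2.88), Col6a2 (2.67), Col1a1 (1.88) and Col5a2 (1.3). Signalling and contractile genes include Rgs4 (5.32), Sfrp2 (5.11), Nkd2 (5.00), Mylk (4.57), Tagln (2.32), Npr3 (4.43), Igf2 (3.90), Bmp4 (3.63) and Fas (3.05), and genes of amines, lipids and energy Aoc3 (5.14), Lpl (3.35), Ndufa13 (1.65), Pfkfb3 (1.39) and Echs1 (1.22). Cytokine and early response genes include Il1rn (3.74), Cxcl5 (3.63), Cxcl1 (3.04), Ccl2 (2.30), Ccl7 (2.13), Egr2 (1.99), Fos (1.64), Csf1 (1.59) and Parp14 (1.89).

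Negative differences include Nptx1 (−6.46), Sema3c (−4.96), Msln (−4.64), Slc14a1 (−4.56), Klhl30 (−4.13), Krt80 (−3.91), Prrg4 (−3.85), Nefl (−3.17), Serpinb9b (−3.10), Il2rg (−3.06), Bcap29 (−2.13) and Tmem132a (−2.26). Muscle genes there include Xirp2 (−3.73), Tmem182 (−2.98), Itga7 (−2.42), Synpo2l (−2.27), Cdh15 (−1.88), Ttn (−1.67) and Ryr1 (−1.41). Stress response genes include Atf3 (−3.15), Stc2 (−3.07), Psat1 (−3.01), Fgf21 (−2.72), Chac1 (−2.16), Creld2 (−1.88), Nqo1 (−2.0) and Cat (−1.19), and cell cycle and p53 genes Pmaip1 (−2.36), Cdkn1a (−2.34), Ccne2 (−2.34), Rrm1 (−1.79), Ccna2 (−1.72), Tpx2 (−1.42) and Plk2 (−1.28). Metabolic and mitochondrial genes include Cox6a1 (−2.07), Ahcy (−1.96), Mrps6 (−1.89), Mrps27 (−1.86), Gpi1 (−1.74), Ndufs8 (−1.51), Cpt1b (−1.50), Gapdh (−1.44), Acadl (−1.37) and Mrpl37 (−1.23), and Zc3h10 (−1.68) and Tfrc (−1.40) close the list.

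The pattern weighed is this opposite direction: of 452 genes called in both kinds of RNA, 99.8% went opposite ways. A biological explanation, opposite effects on RNA synthesis and on stability, needs unspliced RNA in total RNA to move with that in 4sU RNA. Both intron changes instead correlated at −0.832 over 1234 genes called in 4sU exons, which argues against it. These genes were picked for their change in 4sU RNA, and over all 13076 genes tested in both introns Pearson's r was −0.41. An exchange of labels over the 4sU libraries was taken to need Zc3h10 to be higher there with the hairpin. It stood the other way, at −0.49 (SE 0.19), but was not called (edgeR's adjusted p = 0.128). This value therefore cannot decide on that exchange. An exchange over the 6 total RNA libraries is a candidate explanation. Each lies with the 4sU group of the other label over 1403 genes called in 4sU RNA. Correlations with the 4sU change were −0.80, −0.70 and −0.59 for those labelled shZc3h10 and 0.71, 0.81 and 0.61 for those labelled scramble. Both group effects already correlate at −0.81 over these genes, so opposite effects without an exchange would give the same signs. Apart from the counts, the file names of all 6 carry the other hairpin, which goes with an exchange. In total RNA Zc3h10 stood higher under the shZc3h10 label (1.04, SE 0.30, in exons and 1.07, SE 0.26, in introns). That goes with an exchange too, though edgeR did not call its exons (adjusted p = 0.0522). The test by library was chosen after the pattern was seen and alone cannot tell an exchange from opposite effects. Opposite effects on synthesis and stability have the intron changes against them, and other opposite effects were not tested. An exchange is thus the candidate that these values go with, but it was not shown.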

How the results depend on the processing

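The settings that left out both libraries numbered 3 or added the intronic percent as a covariate were chosen after seeing the data. The results below are numbers of genes or lists called and differences in intronic share. The cause of each shift was not tested except where named. Of the values per comparison, 85 stayed close and 50 moved further. Counts were close if within 1.5 times, and differences in intronic share if they shifted by less than the larger group SD. Of the values per gene or list under an alternative, 2588 kept their direction and call, 62 gained a call, 484 lost it and 11 had the other sign. The tally includes the sum of both effects, set against their difference. That is another contrast, so its signs and lost calls do not measure stability.

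In total RNA exons, against 889 genes, DESeq2 called 1877, a fit without the filter on low counts 1591, a fit without both libraries numbered 3 called 214, and the covariate left 3. With 1 library left out the count ran from 126 (without scramble library 3) to 2588 (without scramble library 2). The threshold of 1 on log2 kept 848, and a mean of at least 100 counts 801. Total RNA introns, 719 at first, gave 1260 with DESeq2, 359 at the threshold of 1, 1418 without both libraries numbered 3, and 217 to 1048 with 1 library left out.

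4sU RNA exons, 1412 at first, gave 515 at the threshold of 1, 23 with the covariate, and 724 to 1733 with 1 library left out. The covariate correlates at 0.938 with the hairpin in 4sU RNA and at −0.794 in total RNA, so it removes much of the contrast by construction. Under it Creld2, Hspa5 and Ccna2 reversed to 0.56, 0.0548 and 0.0190 on the log2 scale. 4sU RNA introns, 2103 at first, gave 635 at the threshold of 1 and 935 to 2586 with 1 library left out.

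The difference between both effects, 2123 genes, gave 1029 to 3246 with 1 library left out. The sum of both effects, which cancels opposite effects by construction, called 0 by edgeR (1707 at an unadjusted p below 0.05, 78 by DESeq2). The sum had the other sign than the difference for Rgs4 (−0.0460), Lama1 (−0.00753), Nptx1 (0.97), Sema3c (0.84) and Msln (0.11). The same held for Zc3h10 (0.65), Tfrc (0.62) and Cdkn1a (0.53), and edgeR's adjusted p of these sums ran from 0.437 to 0.996. Since the sum is another contrast, this does not reverse the difference. 4sU against total RNA, 10677 genes, kept within 9641 to 10721 with 1 library left out.

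Exons against introns in total RNA, 4 genes, gave 410 with DESeq2, 1 at a mean of at least 100 intronic counts, and 0 to 615 with 1 library left out. In 4sU RNA, 17 genes, DESeq2 called 44, and 2 to 25 were called with 1 library left out. Called lists went from 6 in total RNA to 0 with the estimated correlation and 0 by fry, and from 9 in 4sU RNA to 0 and 3. The lists kept by fry were matrix, cell cycle and p53 genes. With 1 library left out, 4 to 8 lists were called in total RNA and 5 to 9 in 4sU RNA. The difference in intronic share between hairpins ran from −7.16 to −3.89 points in total RNA and from 2.50 to 3.27 points in 4sU RNA, and that of 4sU against total RNA from 54.2 to 56.4 points.

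With the replicate number as a block, the count was 100 for total RNA exons, 217 for total RNA introns, 809 for 4sU exons, 0 for exons against introns in total RNA (1861 at an unadjusted p below 0.05) and 45 in 4sU RNA. Camera then lost p53 targets (adjusted p = 0.0581), immediate early genes (0.112) and contractile genes (0.0581) in 4sU RNA. With the block it called 7 lists there, 6 of them among the 9 called without it. The other counts stayed within 1.5 times. Libraries with the same number showed no steady link across hairpins: their deviations correlated at 0.25, −0.21 and −0.21 in total RNA and −0.17 and −0.22 in 4sU RNA. The block also costs residual degrees of freedom. Between 4sU and total RNA of a hairpin the same number gave −0.05 to 0.36.

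Simulated changes of 4-fold, 2-fold and 1.5-fold were recovered by edgeR for 98.5%, 23.9% and 0% of genes in total RNA exons and 100%, 92.5% and 47.8% in 4sU exons. For exons against introns in total RNA, 68.2% were recovered at 4-fold. A gene not called in total RNA can thus still have changed by 2-fold. The alternatives with another pseudocount were not run, since the files hold counts.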

Other observations

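The comparison of other replicate pairs in total RNA was chosen after its pattern was seen, while the test of the unspliced share was planned, as were those of GC content, transcript length, transcription against processing, and the splits of the libraries.

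The change of exons in newly made RNA was present in unspliced RNA: of 1264 genes called in 4sU exons that were also tested in introns, 98.4% moved the same way in introns, and the median ratio of the intron to the exon change was 0.879. Fgd4 (1.24, SE 0.13) and Itga3 (−1.02, SE 0.14) were exceptions in which exons changed beyond introns. Introns took 69.9% of counts in 4sU RNA, so exonic counts may come in large part from the same unspliced RNA. Agreement of both parts would then be partly built in. Exons and introns were each scaled on their own, so a shift in splicing shared by many genes would not show. The intronic share itself was 71.0% under the shZc3h10 label and 68.1% under scramble. The values show that both parts changed together, and cannot tell transcription from splicing or decay within the 30 min of labelling. Exonic and intronic counts of a library share its recovery on streptavidin, and a shift in that recovery between groups stays open.

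The total RNA libraries labelled scramble spread widely, from 1.82 (library 2) to 56.3 (library 3) on the first principal component, with 56.9% of the variance. Across genes, the difference between scramble library 3 and scramble library 1, which had the highest and the lowest intronic share, followed the ratio of 4sU to total RNA (Spearman's rho 0.373). It did not follow GC content (rho −0.00708), which argues against a GC bias as its source, while transcript length (0.263) lay between the bounds set for either answer. With length, scramble library 2 minus 3 gave a rho of 0.0187 and library 1 minus 2 gave −0.203, so length stays undecided. A candidate explanation is therefore a varying share of unspliced and newly made RNA in these libraries, and scramble library 2 minus 3 (rho −0.338, 16.2% against 21.9% intronic) and shZc3h10 library 1 minus 2 (0.377, 13.8% against 10.7%, but also −0.271 with GC content and 0.273 with length) go the same way. Scramble library 1 minus 2 goes the other way (0.157, 15.3% against 16.2%), shZc3h10 libraries 1 and 2, each minus 3, gave weak values (0.0874 and −0.136), and no biological explanation was tested, so this stays open.

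Splits of the 6 total RNA libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 889 genes in exons, 719 in introns and 4 for exons against introns, each time as 1 split of the 10, and the highest other split called 0 in each. By edgeR those 3 counts come with 3722, 2480 and 2150 genes at an unadjusted p below 0.05 in the real split. For gene lists the real split called 6, and 6 of the 10 splits called as many. The highest, with shZc3h10 libraries 1 and 2 and scramble library 1 on a side, called 17, and its cause was not tested. For 4sU against total RNA, 1 of 100 drawn splits, the real one, reached its 10677 genes, and the highest other split called 8693. Only 4sU RNA was recovered on streptavidin, so the preparation set this outcome and nothing is concluded from it.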
